A study of Mus musculus with 15 samples.

How the data were processed

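Gene expression was measured by RNA-seq in prefrontal forebrain cortex of 15 mouse libraries in 4 groups. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with the TruSeq Stranded mRNA LT kit. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner, the counting tool and whether counting used strand are not given in the sources used here, so genes that overlap on opposite strands or share sequence with a near-identical copy cannot be told apart with certainty.

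The authors deposited 1 table per library with FPKM values per gene. The deposited FPKM values of the tested genes were whole multiples of the value of 1 read (100% within a tolerance of 0.02 reads), which gave the total reads in genes per library, 16334914 to 19469257. FPKM totals per library ranged from 295704 to 319232. The tables held 21878 rows, of which 3760 were at 0 in every library. The names of 27 genes had been turned into dates and were restored from their gene numbers. Gene numbers matched a RefSeq table of the same build for 21727 rows and did not for 151. Mitochondrially encoded genes were not analysed here.

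Groups were taken from the labels. Values were analysed as log2(FPKM + 1) for the 12728 genes with at least 1 FPKM in at least 3 libraries. The plan named a count model for counts and limma for FPKM. Since the values are FPKM, limma 3.58.1 in R 4.3.3 was used, with an intensity trend, on all 15 libraries in 1 fit with a term per group and no block, and Benjamini-Hochberg adjustment within each of the 6 comparisons. Of 54 gene lists fixed before the data were examined, 51 had at least 5 measured genes. They were tested by camera with a preset correlation of 0.01, adjusted over lists within a comparison, and by camera with an estimated correlation and fry. Lists overlap: Clec7a, Ctss and Cd68 each stand in more than 1. Correlations of fold changes were computed across genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

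Named genes followed a rule fixed before the data were examined. Targeted genes came first. Some genes that the rule names are not reported here. For each comparison of groups, genes with a call, a mean of at least 1 FPKM in the higher group and no overlap between libraries were ranked, and the 8 largest rises and 8 largest falls were taken, leaving out models without a gene name. From each described list up to 4 called members with the smallest p were taken, or up to 2 members with the highest mean where none was called. Nicotinic receptor subunits with a mean of at least 1 FPKM were added. For the interaction, with fewer than 5 calls, the 5 genes with the smallest p were named. Which lists to describe was chosen after their results were seen. Nr1d2, Arntl and Npas2, Kdm5c and Ddx3x were singled out after their values were seen.

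The functions were tested on simulated reads drawn from the means, spread and totals of the real libraries, with 200 of 12728 genes changed. For nicotine vs water in DKO, 56% of genes changed 1.25-fold, 84% of those changed 1.5-fold and 96% of those changed 2-fold were recovered. For the interaction the shares were 36%, 70% and 88%. Each gene was given the same spread in every group, and genes were drawn independently. The real DKO nicotine libraries lay further apart than those of the other groups, so shares for comparisons that use them may be too high.

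Alternatives planned before the data were examined were median-of-ratios rescaling, no filter and a filter at 5 FPKM, no intensity trend, a pseudocount of 0.1, only the groups compared, a replicate block, a 2-fold threshold, protein-coding genes only and leaving out each library. Limma voom on the recovered reads, and autosomal genes only, were added after seeing the data. No result uses a covariate for Y-linked expression, since it would group libraries by their own values.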

Results

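RNA-seq of prefrontal forebrain cortex was carried out on 15 libraries from conditional double knockout mice (DKO) and wild-type C57BL/6J mice (WT). Psen2, a targeted gene, encodes a catalytic subunit of gamma-secretase, the protease complex that cuts the amyloid precursor protein and Notch. The mice were 8 months old when they began to drink water or nicotine at 100 µg/ml, for 3 months. There were 4 WT water, 4 WT nicotine, 4 DKO water and 3 DKO nicotine libraries. Total reads in genes ranged from 16334914 to 19469257 per library, and 1 FPKM of a gene of median length stood on 65.3 reads. The labels do not give the sex of the mice. They number the libraries within a group without saying that each came from a separate mouse, so the p-values measure the spread between these libraries. Fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes, and a call is a Benjamini-Hochberg adjusted p under 0.05 in limma over 12728 genes. The first principal component held 64% of the variance and separated the genotypes.

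The targeted gene Psen2 was examined first. Psen2 (gene 19165, chromosome 1, 180227004 to 180263467, GRCm38.p6) was at 6.43 ± 0.77 FPKM in WT water (SD, n = 4), 6.48 ± 0.571 in WT nicotine (SD, n = 4), 1.51 ± 0.179 in DKO water (SD, n = 4) and 1.57 ± 0.199 in DKO nicotine (SD, n = 3). Every DKO library lay below every WT library.

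**Figure D1:**
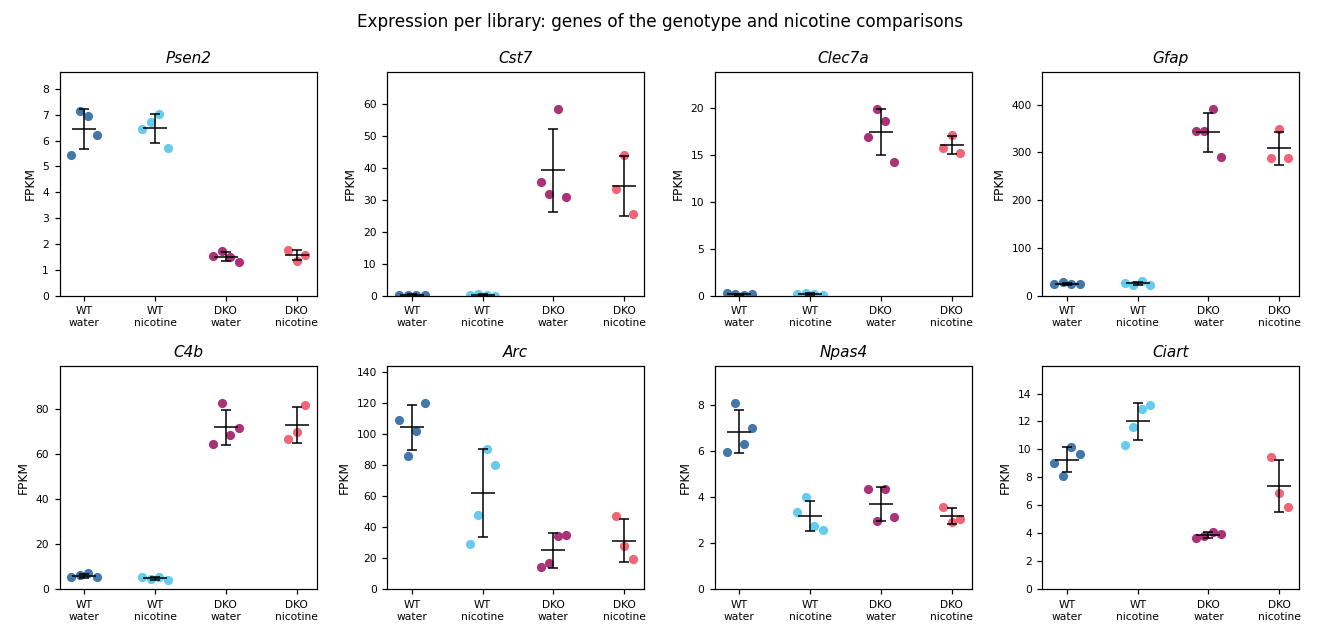
FPKM per library (y axis, linear, from 0) of 8 genes in the 4 groups (x axis). Points are libraries, horizontal bars are group means and error bars are 1 SD (n = 4, and n = 3 in DKO nicotine). Psen2 lay at 1.51 FPKM in DKO water against 6.43 in WT water, and Gfap at 342.0 against 25.2.

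The comparison of DKO with WT mice that drank water asks what the knockout does without nicotine. Microglial, complement, astrocyte and lysosomal genes were higher in the knockout cortex, and clock and protocadherin genes were lower. Immediate early genes went both ways, with 23 of 36 falling and 6 rising, and their list lost its call with an estimated correlation (adjusted p = 0.328). The 8 largest rises without overlap between libraries were in Cst7, Clec7a, Gfap, C4b, Itgax, Lyz2, Lag3 and Serpina3n, by 2.65 to 4.92 on the log2 scale. Cst7, which encodes the protease inhibitor cystatin F, rose from 0.285 ± 0.118 to 39.1 ± 12.9 FPKM (SD, n = 4 each), a log2 change of 4.92 (SE 0.18, limma adjusted p = 3.69e-12). Clec7a, the receptor dectin-1, rose from 0.169 ± 0.0585 to 17.4 ± 2.44 FPKM, and Gfap, the intermediate filament of astrocytes, from 25.2 ± 2.15 to 342.0 ± 40.6. The largest falls were in Arc, Nr4a1, Psen2, Fos, Egr1, Frzb, Junb and Plk5. Arc, an activity-regulated synaptic gene, fell from 104.0 ± 14.3 to 25.0 ± 11.2 FPKM, a log2 change of -2.11 (SE 0.34, limma adjusted p = 0.000123).

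Of 33 measured genes of disease-associated microglia, 32 rose and 1 was not called, and 32 rose when adjusted over the list alone. Their median log2 change was 1.603 (camera adjusted p = 1.45e-28, and 0.00872 with an estimated correlation). Ctss rose from 48.5 ± 2.55 to 220.0 ± 14.2 FPKM, Cd9 from 25.6 ± 2.63 to 96.0 ± 4.31 and Apoe, a lipid carrier, from 753.0 ± 52.0 to 2320.0 ± 198.0. All 33 genes of phagocytosis and Fc receptors rose, over all genes and adjusted over the list alone, among them Cd68 from 6.92 ± 0.209 to 41.1 ± 3.93 and Tlr2 from 0.38 ± 0.115 to 4.81 ± 0.497 FPKM. Rescaling by median-of-ratios factors left 32 of them called. Of 16 complement genes, 12 rose and 4 were not called, and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.1e-08, and 0.0326 with an estimated correlation). C4b rose from 6.03 ± 0.913 to 72.0 ± 7.78 FPKM, and C1qa, C1qb and C1qc, which form the C1q molecule, rose by 2.63, 2.6 and 2.31 on the log2 scale. Of 26 reactive astrocyte genes, 19 rose and 7 were not called, and 22 rose adjusted over the list alone. Serpina3n rose from 7.67 ± 0.404 to 53.8 ± 8.62 FPKM and Aspg from 0.883 ± 0.0556 to 4.79 ± 0.669. General markers of these cell types moved too: of 20 astrocyte markers 20 rose, also adjusted over the list alone (median log2 change 0.369, adjusted p = 0.0803 with an estimated correlation), and of 16 genes of homeostatic microglia 13 rose and 1 fell, also adjusted over the list alone (median 0.804, adjusted p = 0.0933 with an estimated correlation). Of 42 lysosomal genes, 35 rose, 1 fell and 6 were not called, and 36 rose and 1 fell adjusted over the list alone. Npc2, a cholesterol-binding protein of lysosomes, rose from 15.9 ± 0.192 to 33.5 ± 0.895 FPKM. Of 23 cytokine and chemokine genes, 18 rose, 1 fell and 4 were not called, and 20 rose and 1 fell adjusted over the list alone. Ccl6 rose by 2.2, Ccl3 by 2.47 and Tgfb1 by 1.31 on the log2 scale. Of 34 interferon response genes, 22 rose and 12 were not called, and 23 rose adjusted over the list alone. The call of that list was lost with an estimated correlation (adjusted p = 0.328). Irf8, a transcription factor of microglia, rose by 1.66. The lists of astrocyte reactivity, lysosome and cytokines kept their calls with an estimated correlation, at adjusted p = 0.0422, 0.0154 and 0.0346.

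Of 36 immediate early genes, 23 fell, 6 rose and 7 were not called, with the same counts adjusted over the list alone. The call of the list was lost with an estimated correlation (adjusted p = 0.328). Egr1 fell from 134.0 ± 12.8 to 48.8 ± 11.2 FPKM, whereas Nptx2, a secreted pentraxin of excitatory synapses, rose by 1.42, Jun by 1.13 and Gadd45g by 0.64 on the log2 scale. Of 18 clock genes, 12 fell, 1 rose and 5 were not called, and 13 fell and 1 rose adjusted over the list alone (adjusted p = 0.0339 with an estimated correlation). Ciart fell from 9.26 ± 0.904 to 3.88 ± 0.203 FPKM, Bhlhe40 from 61.5 ± 4.31 to 34.8 ± 1.63 and Hlf from 52.2 ± 1.57 to 31.9 ± 1.84. The hour of dissection is not given in the sources used here, so a difference in hour between the groups stays open for these clock genes. Of 45 protocadherins, 21 fell, 2 rose and 22 were not called, and 24 fell and 2 rose adjusted over the list alone (adjusted p = 0.0339 with an estimated correlation). Protocadherins are adhesion genes, and some clustered members share 3' exons, so reads may be shared between those members. Pcdhga8 fell from 4.05 ± 0.406 to 2.02 ± 0.196 FPKM. Of 45 genes of glutamate receptors and the postsynapse, 23 fell, 7 rose and 15 were not called, and 24 fell and 8 rose adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). Grm2 fell from 24.2 ± 1.95 to 12.9 ± 1.08 FPKM and Camk2a from 725.0 ± 8.43 to 517.0 ± 33.2. Of 30 markers of excitatory neurons, 14 fell, 2 rose and 14 were not called, and 15 fell and 2 rose adjusted over the list alone (adjusted p = 0.0184 with an estimated correlation). Lamp5 fell from 98.4 ± 3.29 to 51.7 ± 9.38 FPKM and Neurod6 from 46.0 ± 3.73 to 28.3 ± 2.92. Of 28 oligodendrocyte and myelin genes, 16 rose, 1 fell and 11 were not called, and 17 rose and 1 fell adjusted over the list alone (adjusted p = 0.496 with an estimated correlation). Trf, which encodes transferrin, rose from 126.0 ± 4.96 to 203.0 ± 16.9 FPKM. Among the nicotinic receptor subunits, Chrna4 fell from 12.1 ± 0.865 to 9.56 ± 0.694 FPKM (limma adjusted p = 0.002), whereas Chrna7 lay at 5.9 ± 0.65 against 6.32 ± 0.743 and Chrnb2 at 13 ± 0.611 against 12.6 ± 0.574. That list, in which Chrna4 and Lynx1 fell and 5 of 7 were not called, did not pass camera (adjusted p = 0.119), and 2 fell adjusted over the list alone.

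In all, 3252 genes were higher and 1584 lower in DKO water than in WT water, of which 165 at least doubled and 14 at least halved. Of the 4836 calls, 4127 had no overlap between the groups, and 36.5% of all tested genes had none where chance gives 2.86%. The split between higher and lower depended on the scaling: 67.2% of calls were higher with the values as deposited and 48% after median-of-ratios rescaling, with 2322 higher and 2517 lower. Of the 4836 genes, 3906 were also called after rescaling. List counts for this comparison are for the values as deposited unless rescaling is named, and those of lists with small changes may depend on the scaling.

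The comparison of the genotypes among mice that drank nicotine asks whether the knockout profile is the same under the drug. It named largely the same kinds of genes. Cst7, Clec7a, C4b and Gfap rose by 4.75, 3.82, 3.68 and 3.54 on the log2 scale (SE 0.2, 0.09, 0.11 and 0.11), and Frzb, Egr1, Bok, Ddit4l, Plk5, Rapgef4 and Lamp5 fell by 1.33, 1.13, 1.07, 1.07, 1.05, 1.03 and 1.03. Arc, Nr4a1, Fos and Junb, among the largest falls in water, had libraries that overlapped between the nicotine groups. Arc was at 31.3 ± 14.1 FPKM in DKO nicotine (SD, n = 3) and 61.7 ± 28.3 in WT nicotine (SD, n = 4). Of the disease-associated microglia genes, 31 of 33 rose, over all genes and adjusted over the list alone. Of the complement genes 13 of 16 rose, also adjusted over the list alone (adjusted p = 0.0319 with an estimated correlation). Of the reactive astrocyte genes 18 of 26 rose, and 19 adjusted over the list alone (adjusted p = 0.05 with an estimated correlation). Of the lysosomal genes 35 of 42 rose and 1 fell, and 37 rose and 1 fell adjusted over the list alone (adjusted p = 0.019 with an estimated correlation). Of the interferon response genes 25 of 34 rose, and 28 adjusted over the list alone, a call lost with an estimated correlation (adjusted p = 0.22). Of the protocadherins 20 of 45 fell and 2 rose, and 24 fell and 2 rose adjusted over the list alone (adjusted p = 0.0345 with an estimated correlation). Of the glutamate receptor and postsynapse genes 24 of 45 fell and 8 rose, and 26 fell and 8 rose adjusted over the list alone (adjusted p = 0.116 with an estimated correlation). Immediate early genes went both ways: 11 fell, 8 rose and 17 were not called, with 15 falling and 8 rising adjusted over the list alone. The call of that list was lost with an estimated correlation (adjusted p = 0.582), after rescaling (camera adjusted p = 0.0955) and with a filter at 5 FPKM (camera adjusted p = 0.0555), where Protocadherins also lost theirs (camera adjusted p = 0.0503). Of the clock genes 9 of 18 fell and none rose, and 11 fell adjusted over the list alone (adjusted p = 0.0522 with an estimated correlation). Eif2s3y, on the Y chromosome, was at 10.8 ± 9.26 FPKM in DKO nicotine (SD, n = 3) and 0.0434 ± 0.0194 in WT nicotine (SD, n = 4). Y-linked genes were expressed in 2 of 3 DKO nicotine libraries and none of 4 WT nicotine libraries. Every genotype difference among the nicotine libraries therefore goes in part with Y-linked expression. Chrna4 was at 8.92 ± 0.185 FPKM against 12.4 ± 1.37 and fell (limma adjusted p = 0.000306), as did Lynx1. That list, with 2 of 7 falling, also adjusted over the list alone, passed camera (adjusted p = 0.00722) and lost the call with an estimated correlation (adjusted p = 0.0846). In all, 3133 genes were higher and 1405 lower, and 45.3% of calls were higher after rescaling against 69% before. As in water, the list counts are for the values as deposited, and those of lists with small changes may depend on the scaling. The 2 genotype comparisons shared 2303 genes called higher, where independent lists would share 800, and 1074 called lower, where independent lists would share 175. No gene was called in opposite directions by limma. Across all tested genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.893 and Spearman rho = 0.81.

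The comparison of nicotine with water in WT mice named 22 genes. Klf4 and Klf2, transcription factors of vascular endothelium, rose from 1.91 ± 0.293 to 3.85 ± 0.356 FPKM and from 5.77 ± 0.655 to 10.1 ± 1.61 (SD, n = 4 each; limma adjusted p = 0.000529 and 0.00913). Slc2a1, a glucose transporter of the blood-brain barrier, rose from 32.6 ± 0.522 to 44.0 ± 5.12 FPKM, and Ucp2, Gimap6 and Xdh rose by 0.54, 0.51 and 0.45 on the log2 scale. Npas4, an activity-regulated transcription factor, fell from 6.82 ± 0.936 to 3.17 ± 0.65 FPKM, and Mex3b fell by 0.44 on the log2 scale. Serpinb6a fell from 13 ± 3.11 to 2.28 ± 0.298 FPKM (log2 change -2.07, SE 0.13, limma adjusted p = 4.25e-07) and Gabra2, a GABA receptor subunit, from 19.9 ± 4.56 to 9.63 ± 0.207 (log2 change -0.96, SE 0.1, limma adjusted p = 0.000222). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were near 0 in all 4 WT nicotine libraries and expressed in all 4 WT water libraries. Ddx3y was at 0.0445 ± 0.0172 against 12 ± 1.36 FPKM. The X-linked genes Eif2s3x and Kdm6a rose by 0.57 and 0.36 on the log2 scale. All 22 calls had no overlap between the groups, where chance gives 2.86% of genes and 5.8% of all tested genes had none. Every difference between these WT groups goes with the difference in Y-linked expression, and 15 genes were called among autosomal genes alone. Xdh, Kdm6a, Mex3b, Ly6c1 and Bhlhe41 each lost the call when at least 1 of the libraries was left out, and the 4 Y-linked genes and Gimap6 lost it with limma voom.

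**Figure D2:**
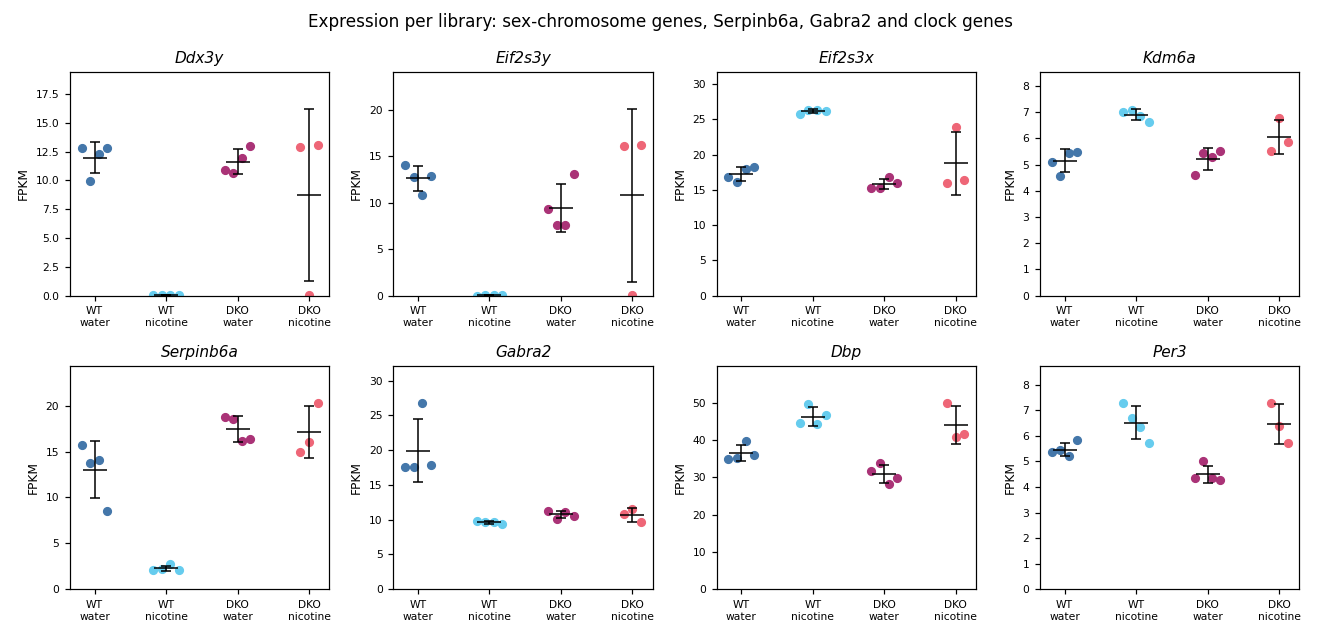
FPKM per library (y axis, linear, from 0) of 8 genes in the 4 groups (x axis). Points are libraries, horizontal bars are group means and error bars are 1 SD (n = 4, and n = 3 in DKO nicotine). Ddx3y was below 0.1 FPKM in the 4 WT nicotine libraries and in DKO nicotine replicate 2, and at 9.96 FPKM or more in the others.

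Of 36 immediate early genes, Klf4 and Klf2 rose and Npas4 fell in WT, and 2 rose and 8 fell adjusted over the list alone. The mean log2 value of that list was 3.32 and 3.5 in WT nicotine replicates 1 and 2, below the 3.75 to 3.95 of WT water, and 3.79 and 3.84 in replicates 3 and 4, within it. Of 28 endothelial and pericyte genes, Slc2a1 and Ly6c1 rose, with 2 adjusted over the list alone. Of 18 clock genes, Bhlhe41 rose from 8.6 ± 0.678 to 10.8 ± 0.329 FPKM, and 7 rose and 3 fell adjusted over the list alone. No gene of the hormone-responsive, oligodendrocyte, astrocyte or oxidative phosphorylation lists was called over all genes by limma, where 1107 of all tested genes had an unadjusted p under 0.05. Adjusted over the list alone, 4 hormone-responsive genes rose and 1 fell, 2 astrocyte genes rose, 1 oligodendrocyte gene fell and 0 oxidative phosphorylation genes were called. Mt2 was at 80.8 ± 8.96 against 64.3 ± 3.07 FPKM, Mbp at 302 ± 7.57 against 314 ± 18.9, Glul at 674.0 ± 37.0 against 613.0 ± 19.9 and Atp5b at 563.0 ± 10.3 against 578.0 ± 15. These 7 lists passed camera with the preset correlation, and all lost the call with an estimated correlation (adjusted p = 0.586 for the hormone-responsive list and 0.881 for the other 6). Oxidative phosphorylation also lost the call without WT nicotine replicate 1 (camera adjusted p = 0.621), WT water replicate 1 (0.159) or WT water replicate 2 (0.343), and Circadian clock without WT water replicate 2 (0.071). The nicotinic receptor subunits Chrna4, Chrna7 and Chrnb2 were at 12.4 ± 1.37, 6.07 ± 0.54 and 12.4 ± 0.797 FPKM against 12.1 ± 0.865, 6.32 ± 0.743 and 12.6 ± 0.574, without a call.

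The comparison of nicotine with water in DKO mice named 20 genes, 13 higher and 7 lower, and 5 of the higher ones were clock genes. Ciart rose from 3.88 ± 0.203 (SD, n = 4) to 7.39 ± 1.86 FPKM (SD, n = 3), Dbp from 30.9 ± 2.36 to 44.1 ± 5.05, Per3 from 4.5 ± 0.344 to 6.47 ± 0.785 and Bhlhe41 from 8.5 ± 0.396 to 11.1 ± 0.12, with limma adjusted p = 0.0149, 0.0149, 0.0349 and 0.0149. Of 18 clock genes 5 rose and none fell, and 9 rose and 3 fell adjusted over the list alone; the list's call was lost with an estimated correlation (adjusted p = 0.437). Jsrp1, Coq10b, Kcnk9 and Pxdn rose by 0.52, 0.41, 0.39 and 0.37 on the log2 scale. Kcns1, Isyna1, Specc1, Creld1 and Pnkd fell by 0.34, 0.28, 0.27, 0.24 and 0.19. No gene of the oxidative phosphorylation, striatum, oligodendrocyte, hormone-responsive, unfolded protein response or cholesterol synthesis lists was called by limma, where 1765 of all tested genes had an unadjusted p under 0.05. Penk, a striatal marker, was at 52.1 ± 17.7 against 76.3 ± 19.2 FPKM, Atp5b at 520.0 ± 18.6 against 570.0 ± 22.7, Mbp at 288.0 ± 19 against 330.0 ± 34.3, Calr at 166.0 ± 2.58 against 189.0 ± 19.8 and Hmgcs1 at 104.0 ± 6.89 against 91.0 ± 4.57. Adjusted over the list alone, 5 cholesterol genes rose and 1 fell, 1 hormone-responsive gene rose, 1 oligodendrocyte gene fell and 0 of the other 3 lists were called. These 6 lists lost their camera calls with an estimated correlation (adjusted p = 0.799 each). Oligodendrocyte and myelin lost it also without DKO nicotine replicate 2 (0.0766), Hormone-responsive and glucocorticoid without DKO nicotine replicate 1 (0.0636), Unfolded protein response without DKO water replicate 3 (0.0585), and Cholesterol synthesis without DKO nicotine replicate 1 (0.26) or DKO water replicate 3 (0.0658). The endothelial and pericyte list, with a median log2 change of 0.08 in WT, had one of -0.10 in DKO, with 0 of 28 genes called, also over the list alone, Vtn at 46.7 ± 11.9 against 56.1 ± 4.68 FPKM and Slc2a1 at 38.8 ± 3.6 against 35.0 ± 1.91. It passed camera toward lower values (adjusted p = 0.0178), and not with an estimated correlation (0.799), with a filter at 5 FPKM (0.0991) or without DKO nicotine replicate 1 (0.497) or DKO water replicate 2 (0.295). Chrna4, Chrna7 and Chrnb2 were at 8.92 ± 0.185, 5.13 ± 0.207 and 11.9 ± 0.347 FPKM against 9.56 ± 0.694, 5.9 ± 0.65 and 13 ± 0.611, without a call. The count of genes differed between fits: fitted on the DKO libraries alone, limma called 0 genes, with 1335 at an unadjusted p under 0.05, and limma voom on reads recovered from the values called 56. The main fit shares 1 estimate of spread over all groups. Between DKO nicotine libraries the chi-square per gene on the recovered reads, a measure of spread, was 6.87 to 7.73. Between libraries within the other groups it was 3.2 to 6.07. The spread used for DKO nicotine thus came in part from groups whose libraries lay closer. DKO nicotine replicate 2 lacked Y-linked expression, and 3 genes were called without it, 1 without DKO water replicate 1 or 3, and 57 without DKO nicotine replicate 3. All 20 calls had no overlap between the groups, where chance gives 5.71% and 10.9% of all tested genes had none.

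Averaged over genotypes, 56 genes were higher and 28 lower with nicotine than with water, 8 of them on the X or Y chromosome. All WT nicotine libraries and DKO nicotine replicate 2 lacked Y-linked expression, and no water library lacked it. Every difference in this average, on autosomes too, therefore goes in part with Y-linked expression. Dbp, Ciart, Per3 and Nr1d2 rose by 0.42, 0.55, 0.33 and 0.22 on the log2 scale, and Arntl and Npas2, which act in the opposite phase of the clock, fell by 0.23 and 0.13 (limma adjusted p = 0.0393 and 0.0473). Of 18 clock genes 6 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (adjusted p = 0.365 with an estimated correlation). Of 22 hormone-responsive genes 4 rose, and 10 rose adjusted over the list alone (adjusted p = 0.365 with an estimated correlation). Limma called 66 genes on autosomes only, an alternative chosen after seeing the data, and 171 with voom.

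The interaction asks whether nicotine acts differently in the 2 genotypes. Y-linked expression was absent from all 4 WT nicotine and 1 of 3 DKO nicotine libraries and present in all water libraries, so the interaction goes in part with it. Serpinb6a and Gabra2 passed, with a nicotine effect in DKO above that in WT by 2.03 (SE 0.2, limma adjusted p = 0.00018) and 0.95 (SE 0.15, limma adjusted p = 0.0407) on the log2 scale. Klf4, Dpm3 and Rprm, the next by p, did not pass (limma adjusted p = 0.0625, 0.116 and 0.341). Gabra2 lost its call after rescaling, without the filter on low values, without the intensity trend and when any WT nicotine, DKO nicotine or DKO water library was left out. Serpinb6a kept its call in all of these. Of the lists, 7 passed camera with the preset correlation: the nicotine effect in DKO was below that in WT for the striatum, endothelial and pericyte, astrocyte, unfolded protein response and oxidative phosphorylation lists (median differences of -0.46, -0.18, -0.12, -0.12 and -0.03 on the log2 scale; camera adjusted p = 2.69e-07, 7.93e-07, 1.17e-05, 1.5e-05 and 0.0368) and above it for immediate early genes and cholesterol synthesis (0.26 and 0.11; 0.000236 and 0.000319). None of their genes was called over all genes, and adjusted over the list alone 7 immediate early genes were above and 2 below, 1 astrocyte gene was below, 1 cholesterol gene was above and 0 of the other 4 lists were called. All 7 lost the call with an estimated correlation (adjusted p = 0.947 for oxidative phosphorylation and 0.928 for the other 6). Cholesterol synthesis also lost it without DKO nicotine replicate 1 (0.0683). Oxidative phosphorylation lost it without a filter (0.0522), with a filter at 5 FPKM (0.068), without the intensity trend (0.0577), and without WT nicotine replicate 2 (0.724), WT water replicate 3 (0.0944) or 4 (0.461), DKO nicotine replicate 2 (0.937) or DKO water replicate 1 (0.528) or 2 (0.0586). The striatum list was fixed to watch for dissection, which stays open. Its mean log2 value ranged from 2.73 to 3.5 within WT nicotine and from 3.04 to 3.85 within DKO water. Across all tested genes the nicotine effects in WT and DKO correlated with r = 0.252 and rho = 0.234, and with r = 0.119 without DKO nicotine replicate 2.

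The last comparison asks whether nicotine moved the knockout profile back toward wild type. Across the 4836 genes called between DKO water and WT water, the nicotine effect in DKO and the genotype effect correlated with r = -0.213. Both use the DKO water libraries with opposite signs, and simulated unchanged groups gave r = -0.46 (SD 0.019, 100 simulations). Those groups held noise alone, without a genotype effect, so their r cannot be set directly against -0.213. The covariance was -0.0105 against a simulated -0.0028 (SD 0.00016), a difference of -0.00771. Each gene was simulated independently of the others, so both SDs are too small where genes vary together. With the DKO water libraries split so that each effect used its own pair, r ranged from -0.235 to -0.029 over the 6 splits, with a median of -0.137. The genes were still those called with all DKO water libraries, so the noise of both pairs helped to choose them. The split does not remove that part of the bias toward a negative r. Over all DKO water libraries r was -0.069 without DKO nicotine replicate 1 and -0.142 without DKO water replicate 2. These values are across genes, which are not independent replicates, and carry no test.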

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

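The tests on Y-linked genes, on the steps of Gabra2, on Serpinb6a in a single library, on the WT part of the clock genes and on the signs of clock genes, and the estimated correlation, fry and the values per library for the DKO part, were chosen after the results were seen. The splits of libraries, the neighbours of Serpinb6a and Gabra2 and the DKO part of the clock genes were set before their results were seen.

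Regrouping the libraries tested whether chance could give as many calls. For DKO water vs WT water 1 of 35 splits, the labelled one, gave 4836 genes, and the highest of the others gave 0. For DKO nicotine vs WT nicotine it was 1 of 35, with 4538 genes and 1864 in the highest other, a split that differs from the labelled one in a single WT library. For nicotine in WT it was 1 of 35, with 22 genes and 5 in the highest other, and for nicotine in DKO 1 of 35, with 20 genes and 3. For the average over genotypes it was 1 of 100 drawn splits, with 84 genes and 31. In these 5 comparisons no other split tried called as many genes. A share of 1 in 35 is the smallest that 35 splits can give. Between the genotypes, a mixed split adds the genotype difference to the spread and so calls fewer genes by construction. For nicotine in DKO, limma called 0 genes when fitted on the DKO libraries alone, so chance stays open for that count. A split by treatment in WT is also a split by Y-linked expression. For the interaction 9 of 100 drawn splits gave 2 genes or more, and the highest other gave 5, so chance cannot be excluded for that count.

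Y-linked genes differed between libraries of one drug. A water library without Y-linked expression was taken as the sign of exchanged libraries, and 0 of 8 were without it. That cannot exclude an exchange: one that moved libraries without Y-linked expression out of water would also leave 0. A response to nicotine would lower Ddx3y in the 3 DKO nicotine libraries, but 2 of 3 had it at 1 FPKM or more. All 4 measured X-linked genes that escape inactivation, Kdm6a, Eif2s3x, Ddx3x and Kdm5c, were higher in every WT nicotine than in every WT water library, which is consistent with female mice in the WT nicotine group and male mice in the WT water group. The labels give no sex, so sex and nicotine are confounded in WT, and the 15 autosomal calls there stay open to both.

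The nicotine effect on Serpinb6a and Gabra2 differed between genotypes by an interaction test, by 2.03 and 0.95 on the log2 scale. Serpinb6a lies on chromosome 13 at 33917918 to 34002794 and Gabra2 on chromosome 5 at 70958392 to 71095849 (GRCm38.p6), and Gabra2 in WT water replicate 3, at 26.8 FPKM, stood apart from the other WT water libraries at 17.6 to 17.8, and the other 3 groups lay between 9.32 and 11.6. The 3 lower WT water values differed by -4.79% from the midpoint between the highest value and the mean of the other groups, as a variant carried in 1 or 2 copies might give, and C57BL/6J is known to carry a deletion that lowers Gabra2. On that account the WT water mice, given as C57BL/6J, would be those without the deletion. Such a difference would then also separate WT water from DKO water, where Gabra2 was at 10.7 ± 0.547 FPKM (SD, n = 4) against 19.9 ± 4.56. That was not tested. Of 75 tested neighbours within 5 Mb of either gene, 14.7% had an unadjusted p under 0.05 (exact Clopper-Pearson 95% interval 7.56 to 24.7) against 8.7% of all genes. Near Serpinb6a 8 of 42 had it, and near Gabra2 3 of 33. The pooled share was under 2 times that of all genes (17.4%), the outcome set beforehand against a longer segment of another strain. The interval, which was not part of that rule, reaches above 17.4%, so such a segment stays open. Sex and a response to nicotine in WT stay open too: Serpinb6a was at 16 FPKM in DKO nicotine replicate 2, within the 15 to 20.3 of the other DKO libraries, but that is a single library.

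The clock list differed between nicotine and water in both genotypes with the preset correlation, and lost the call with an estimated correlation (adjusted p = 0.437 in DKO and 0.881 in WT). Without the DKO library lacking Y-linked expression, camera with the preset correlation gave an adjusted p of 0.00023 and a median log2 change of 0.137, the outcome set beforehand against sex. The median was 0.154 with all libraries, and the list's mean log2 value was 4 and 3.84 in the other 2 DKO nicotine libraries against 3.72 to 3.78 in DKO water, which argues against sex as the whole cause in DKO but does not exclude it: the preset value is below the correlation of 0.107 estimated for the list, and fry, with 2 nicotine libraries left, gave an adjusted p of 0.0701 (unadjusted 0.00137) against 0.0106 with all. In WT, all 4 nicotine libraries lacked Y-linked expression, so sex cannot be told apart from nicotine. The hour of dissection is not given in the sources used here and stays open: 12 of 12 fold changes of Dbp, Ciart, Per3, Nr1d2, Arntl and Npas2 had the sign of a shift of phase, but some of these genes were picked after their values were seen, so the count decides nothing.

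Among 360 groups of 4 libraries of the named genes, 22 held a library far from the other 3, where chance gives about 18. In WT water, replicate 3 was high in Neurod6 (51.6 FPKM), Bhlhe41 (9.6), Cry2 (47.9), Dpm3 (10.4) and Gabra2 (26.8). Replicate 2 of WT water was high in Cyp46a1 (81.8 FPKM) and Bok (31) and low in Coq10b (15.3), and replicate 4 was high in Pxdn (11.3). In WT nicotine, replicate 1 was low in Klf2 (7.66 FPKM), Eif2s3x (25.8) and Hsp90b1 (128), replicate 2 was high in Cox8a (513), replicate 3 was high in Irf9 (3.52), and replicate 4 was low in Lag3 (3.44) and Rorb (4.22). In DKO water, replicate 2 was low in Grm2 (11.3 FPKM) and Chrnb2 (12.1) and high in Per3 (5.01), replicate 3 was high in Cst7 (58.2), and replicate 4 was high in Gadd45g (15) and low in Ddit4l (4.27).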

How the results depend on the processing

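No called value among the named genes, the described lists and the counts and correlations reported changed sign under any alternative run; other genes were not followed one by one. The total counts for both genotype comparisons stayed within 1.5 times, except with a 2-fold threshold, which left 179 and 174 genes. Their split moved: after rescaling 2322 genes were higher and 2517 lower in water, against 3252 and 1584, and 2001 and 2413 in nicotine, against 3133 and 1405. The 2-fold threshold left 5 genes for nicotine in WT, 0 in DKO, 1 for the interaction and 5 for the average, by its construction. For nicotine in DKO, limma gave 13 genes without the trend and 0 with only the groups compared (1335 at an unadjusted p under 0.05), and voom gave 56. For the average it gave 39 genes without a filter and 171 with voom. For the interaction 1 gene remained after rescaling, without a filter and without the trend. Apart from construction, the cause was not tested. Replicate numbers did not pair the libraries: correlations of same-numbered residuals ranged from -0.214 to 0.165 and 2 of 15 libraries correlated best with their own number. The replicate block gave 4620, 19, 15, 3980, 1 and 46 genes for DKO vs WT in water, nicotine in WT, nicotine in DKO, DKO vs WT in nicotine, the interaction and the average, and 11 lists for the interaction.

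With an estimated correlation 15 lists passed for DKO water vs WT water against 32, 10 for DKO nicotine vs WT nicotine against 31, and 0 for nicotine in WT, nicotine in DKO, the interaction and the average against 8, 12, 7 and 6. With fry, 0, 1, 0 and 2 lists passed for these 4. The correlation of genotype effects was 0.911 with the stricter filter, and that of nicotine against genotype -0.137 with split controls.

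Leaving out each library gave 4063 to 4932 genes for DKO vs WT in water, 17 to 28 for nicotine in WT, 3429 to 4517 for DKO vs WT in nicotine, 1 to 6 for the interaction, 36 to 209 for the average and 1 to 57 for nicotine in DKO. In DKO, 1 gene was called without DKO water replicate 1 or 3, 3 without DKO nicotine replicate 2 (2 of them among the 20), 6 without DKO nicotine replicate 1 (4 among the 20), and 57 (17 among the 20) without DKO nicotine replicate 3; the counts were 8 to 10 without WT nicotine replicates 1, 2 and 3, WT water replicates 1 and 4 or DKO water replicate 2. For the average, 209 genes were called without DKO nicotine replicate 3 and 36 to 54 without WT nicotine replicates 1 and 3, WT water replicates 1 and 3, DKO nicotine replicate 2 or DKO water replicates 1, 2 and 3. For the interaction, 6 genes were called without DKO nicotine replicate 2, 3 without WT water replicate 1, and 1 without any of the WT nicotine or DKO water libraries or DKO nicotine replicate 3. Lists passing ranged from 31 to 33, 6 to 12, 9 to 17, 30 to 32, 6 to 14 and 5 to 12 for DKO vs WT in water, nicotine in WT, nicotine in DKO, DKO vs WT in nicotine, the interaction and the average. Correlations ranged from 0.119 to 0.307 between nicotine effects, 0.869 to 0.896 between genotype effects and -0.292 to -0.069 for nicotine against genotype.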

Other observations

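Other gene groups also differed between DKO water and WT water. All 6 measured genes of MHC class II rose, over all genes and adjusted over the list alone, and 5 of 6 after rescaling (adjusted p = 0.129 with an estimated correlation). Cd74, the invariant chain, rose from 4.16 ± 1.15 to 21.1 ± 1.79 FPKM (SD, n = 4 each), and H2-Ab1 from 1.84 ± 0.724 to 6.08 ± 0.454. Of 25 markers of inhibitory neurons 16 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.408 with an estimated correlation). Vip, a neuropeptide of a class of interneurons, rose from 29.6 ± 2.67 to 64.2 ± 2.52 FPKM, while 14 of 30 markers of excitatory neurons fell. Of 20 striatal markers 9 rose, and 11 rose adjusted over the list alone (adjusted p = 0.639 with an estimated correlation). That list was fixed to watch for dissection, which stays open. Its mean log2 value ranged from 2.76 to 3.21 in WT water and from 3.04 to 3.85 in DKO water. The mean of the inhibitory list ranged from 3.85 to 3.99 and from 4.04 to 4.27. In both groups the libraries lowest and highest on the striatal list were also lowest and highest on the inhibitory list. Dissection therefore stays open for the inhibitory markers too.

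Genes of the Notch pathway, a substrate of gamma-secretase, went both ways. Of 16 measured genes 5 rose, 3 fell and 8 were not called, 6 rose and 3 fell adjusted over the list alone, and the list did not pass camera (adjusted p = 0.697). Mfng, Notch1 and Lfng rose by 0.54, 0.42 and 0.37 on the log2 scale, and Jag2 and Hes5 fell by 0.21 and 0.4. The names in this part were chosen after their values were seen.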
